A study of Mus musculus with 3 samples.

How the data were processed

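Poly(A) RNA of naive B cells from mouse spleen was measured by RNA sequencing in 3 samples. All 3 carried the same genotype, with 1 floxed and 1 wild-type allele of Ctcf and a Cre recombinase knocked in at 1 copy of Cd19, so they formed 1 group and no comparison between groups was possible. A wild-type control was not analysed here. Per the labels' protocols, spleens were passed through a strainer, erythrocytes were lysed, and B cells were left after magnetic depletion of cells that carry CD43. Libraries were made with the TruSeq RNA kit and sequenced as single reads.

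The deposited table holds expected counts per Ensembl gene. Per the submitters' processing notes, the tools were cutadapt, a read trimmer, and RSEM 1.3.1, which divides reads that fit several transcripts between them by an estimated probability, on the mouse build GRCm38. The aligner and whether strand was used in counting were not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. The deposited expected counts were not normalized. The table had 41214 genes, of which 97.9% had a symbol in the GENCODE annotation of the same build, and genes without a symbol held 0.331% ± 0.00917 of the counts (SD, n = 3). Totals were 9991875, 9492814 and 11843664 expected counts in replicates 1, 2 and 3. An observed count of 0 allows an expected count of up to 3, which stood for 0.300, 0.316 and 0.253 CPM, counts scaled to the library total, in these libraries. Such limits cover counting error only, because reads without molecular identifiers are not independent molecules. The list members Ighd, Iglc1, Iglc3, Iglc4, Hbb-b1 and Hbb-b2 were not analysed here.

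Levels within a sample were computed as TPM, a share of transcripts corrected for length, from the deposited expected counts and the median length of each gene's GENCODE basic transcripts, and were taken to the log2 scale with a pseudocount of 0.1. A difference on that scale understates the change of low genes. A gene was called detected with at least 10 expected counts in each of the 3 samples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used. Before the data were examined, 28 gene lists, 22 gene pairs and the tests were fixed. The lists covered cell types (pan-B, follicular B, marginal zone B, early B, B-1, germinal centre, plasma cell, T cell, NK cell, myeloid, dendritic, neutrophil, erythroid, platelet and stroma), B cell functions (transcription factors, B cell receptor signalling, MHC class II, receptors, heavy constant and light constant segments), CTCF and cohesin, cell cycle, quiescence, the BCL2 family, interferon response, immediate early genes and sex-linked genes. The level of a list was the median over its members in each sample. The pan-B and follicular B lists were compared with each other cell type list within each sample by an exact sign-flip permutation test, two-sided, for which 0.25 is the smallest p that 3 samples allow.

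To find genes that varied between samples, expected counts were rounded to whole numbers and fitted in edgeR 4.0.16 (R 4.3.3) with TMM normalization, an intercept and a robust prior. Each gene's quasi-dispersion was divided by the prior of genes of its abundance and tested as an F statistic, one-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Counts were simulated for 12206 genes, of which 200, drawn over all abundances, were changed in 1 sample. The F test recovered 0% of 2-fold, 10.0% of 4-fold, 70.0% of 8-fold and 94.0% of 16-fold changes, with 2 false calls. Most smaller differences would thus be missed. Some were still called in the data, such as Igha at 134.1, 55.2 and 52.9 normalized CPM in replicates 1, 2 and 3. The deviation of a list was its members' mean deviation in the sample where that was largest, given as a percentile among 10000 random lists of the same size and matched abundance. A simulated list of 10 genes raised 2-fold in 1 sample of these 12206 genes lay at percentile 100, and an unchanged list at 41.2.

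The text names the 25 genes with the highest mean level, every member of the CTCF and cohesin list and Cd19, the 4 highest members of every other list, the detected members of lists with few detected members, the genes of the pairs, and the 20 genes with the largest F among those past the threshold. Other genes are named only where said. Reads of immunoglobulin segments, globin copies, ribosomal protein copies and mitochondrial pseudogenes are shared with near-identical sequences, so their single values are uncertain. Alternatives were other normalizations (DESeq2 1.42.0 size factors, library totals), other filters, limma 3.58.1 voom, DESeq2 dispersion outliers, a prior without the robust option, CPM in place of TPM, another pseudocount, the mean over members, and each replicate left out. The exon union length, an erythroid covariate and the removal of globin genes were added after seeing the data. Figures were drawn with matplotlib 3.10.9.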

Results

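The gene expression profile of naive splenic B cells was measured in 3 samples of mice heterozygous for a floxed Ctcf allele and for Cre at Cd19, with the aim of characterising expression in these cells. Cre made from the Cd19 locus acts in the B lineage, and Ctcf encodes the zinc finger protein that shapes chromatin loops with cohesin. The libraries held 9991875, 9492814 and 11843664 expected counts. The labels do not say that the samples came from separate animals, so the spread between them may be technical. They were not copies of one library: over the 12206 detected genes, pairs of samples differed by a mean chi-square of 11.8, 16.1 and 30.8 per gene with 1 degree of freedom each, for replicates 1 and 2, 1 and 3, and 2 and 3. Abundant genes weigh most in such a mean. The median gene had an SD of 0.127 between samples in log2 CPM.

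Ctcf mRNA was present in all samples at 64.8, 67.2 and 72.5 TPM in replicates 1, 2 and 3, a mean of 68.1 ± 3.92 TPM (SD, n = 3), which was the 81.8th percentile of detected genes. The gene lies on chromosome 8 of GRCm38 from 105636568 to 105682922, and its value joins reads of both alleles. The part of Ctcf that Cre removes was not given in the sources used here, so the value does not measure how many cells had lost it. Cd19, on chromosome 7 from 126408450 to 126414889, stood at 643.7 ± 51.0 TPM (SD, n = 3), the 98.3rd percentile. Cre was knocked in at 1 copy of Cd19, and what that copy added to the value was not tested. Ctcfl, the paralog of Ctcf known from the male germ line, had 2, 0 and 3 counts.

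The CTCF and cohesin genes were expressed at moderate levels, with 21 of 24 members detected and a list median of 4.83 ± 0.09 log2 TPM (SD, n = 3). Highest were Ldb1, a cofactor that joins LIM domain proteins at enhancers, at 249.1 ± 30.0 TPM, and the zinc finger gene Maz at 194.6 ± 12.7 TPM. Of the cohesin ring, Rad21 stood at 76.6 ± 5.41, Smc1a at 51.0 ± 2.28, Stag2 at 50.6 ± 2.42, Smc3 at 39.2 ± 0.817 and Stag1 at 20.99 ± 1.58 TPM. The cohesin regulators Esco1, Mau2, Wapl, Pds5a, Nipbl and Pds5b lay between 19.6 ± 1.91 TPM for Pds5b and 68.6 ± 6.67 TPM for Esco1. Yy1 and Zfp143, which also bind at loop anchors, stood at 27.3 ± 1.02 and 22.6 ± 0.995 TPM, and the SMC3 deacetylase gene Hdac8 at 11.6 ± 1.27 TPM. Esco2 and Cdca5, which act in cohesion during S phase, had 129, 206 and 54 counts and 103, 148 and 67 counts in replicates 1, 2 and 3, the same order as the erythroid and cell cycle genes. The meiotic genes Rec8 and Stag3 were near 1.72 and 1.09 TPM, Smc1b had 2, 1 and 7 counts, and Rad21l had 0 in each sample. Stag2 exceeded Stag1 by 1.27 ± 0.04 and Ctcf exceeded Yy1 by 1.32 ± 0.05 on the log2 scale in all 3 samples, and Smc1a exceeded Smc3 in all 3, with a log2 ratio of Smc3 over Smc1a of -0.38 ± 0.05. The log2 ratio of Ctcf over Rad21 was -0.17 ± 0.17, with its sign differing between samples.

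The 25 genes with the highest mean level included mitochondrial, adult globin, ribosomal protein, MHC class II and immunoglobulin constant genes. The mitochondrial genes mt-Co1 at 14418 ± 1779, mt-Atp8 at 7604 ± 816, mt-Cytb at 5724 ± 591 and mt-Nd1 at 5569 ± 738 TPM (SD, n = 3) were among the top 25, along with Cd74, the invariant chain of MHC class II, at 10014 ± 1163 TPM. The translation factor gene Eef1a1 stood at 8272 ± 387 TPM, beta-actin (Actb) at 6175 ± 366 TPM and the actin-binding thymosin gene Tmsb4x at 5111 ± 263 TPM. Ribosomal protein genes in the top 25 ran from Rps3a1 at 3899 ± 372 to Rpl13a at 5633 ± 428 TPM, with Rps24, Rplp1 and Rps27rt between them. The mitochondrial pseudogenes Gm28661, Gm10925 and Gm28437 and the processed pseudogene Gm9843 were also in the top 25. The adult globin genes Hba-a2 at 14328 ± 9581, Hbb-bs at 12529 ± 8413, Hba-a1 at 9204 ± 6166 and Hbb-bt at 5010 ± 3469 TPM had SDs above 60% of their means.

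In all, 12206 genes were detected, of which 11144 were annotated as protein coding, and the median detected gene stood at 20.98 TPM. The 50 most abundant genes took 14.8% ± 1.23 of the counts (SD, n = 3), mitochondrial genes 3.44% ± 0.502, ribosomal protein genes 6.27% ± 0.351 and immunoglobulin segments 1.003% ± 0.00514. The ribosomal share covered 85 genes picked by a symbol pattern that left out Rplp1 and Rps27rt, so part of that class is missing from it. The mitochondrial share left out the pseudogenes Gm28437, Gm10925 and Gm28661, which share reads with mitochondrial genes. These pseudogenes took 1.11% ± 0.167 of the counts. Histone genes, most of whose transcripts lack a poly(A) tail, took 0.0159% ± 0.00217. The adult globin genes took 1.38%, 2.68% and 0.579% in replicates 1, 2 and 3. By shares of TPM, the top 50 held 25.6%.

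Genes of mature naive B cells stood far above those of most other cell types. All 16 pan-B members were detected, with a list median of 8.71 ± 0.09 log2 TPM (SD, n = 3), led by the B cell receptor signal chains Cd79a at 2570 ± 106 and Cd79b at 2006 ± 108 TPM and by Cd37, a tetraspanin gene, at 2272 ± 328 TPM. The follicular B list had 11 of 11 measured members detected and a median of 8.34 ± 0.10, led by Fcer2a, which encodes CD23, at 1506 ± 248 TPM, Ltb at 1141 ± 64.4, Klf2 at 627.3 ± 27.1 and Sell, which encodes L-selectin, at 346.6 ± 48.0 TPM. Marginal zone B genes were lower at 5.77 ± 0.06, led by Cr2 at 206.1 ± 27.0, Dtx1 at 73.9 ± 9.39, Cd1d1 at 65.4 ± 7.98 and Notch2 at 60.4 ± 9.41 TPM. Fcer2a exceeded Cr2 by 2.86 ± 0.10 on the log2 scale in all 3 samples.

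**Figure D1:**
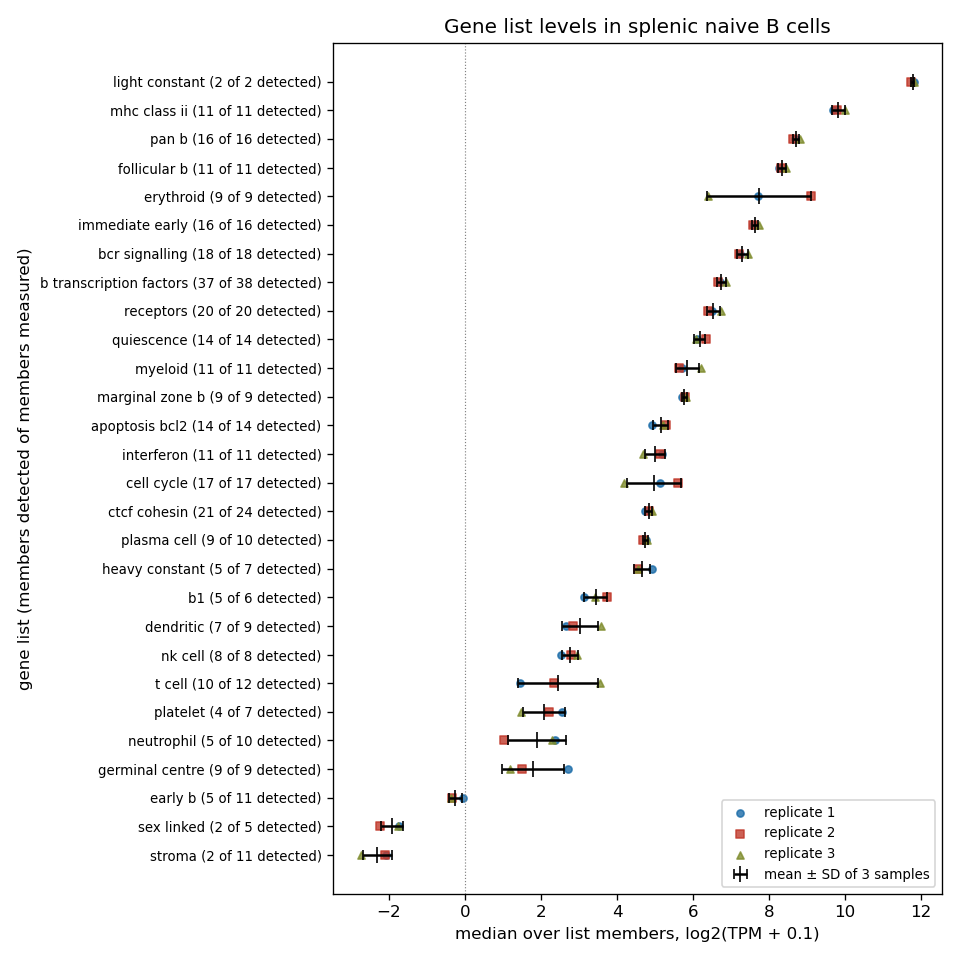
Level of each gene list, as the median of its members in log2(TPM + 0.1) on the horizontal axis, with coloured points for the 3 samples and bars for their mean ± SD. The pan-B list lies at 8.71 and the stroma list at -2.31, and the erythroid list has the widest bar, an SD of 1.36.

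Genes of other B lineage stages were lower. The germinal centre list had a median of 1.80 ± 0.81 log2 TPM (SD, n = 3), with Bcl6 at 54.4 ± 7.24 TPM and Mef2b, Fas and Rgs13 at 7.20 ± 3.15, 6.98 ± 0.773 and 5.71 ± 1.34 TPM. The plasma cell list stood at 4.75 ± 0.06 with 9 of 10 members detected, led by Jchain at 290.6 ± 20.6 TPM, Mzb1 at 289.7 ± 30.4, Xbp1 at 100.9 ± 10.5 and Irf4 at 64.8 ± 3.80 TPM. The early B list had 5 of 11 members detected and a median of -0.26 ± 0.17, a value set by undetected genes, which became 0.80 with a pseudocount of 1, 1.18 by the mean over members and 3.62 over detected members only. The detected members were Cd24a at 1209 ± 285 TPM, which red cells also carry, Vpreb3 at 196.0 ± 22.5, Cd93 at 12.2 ± 0.351, Il7r at 3.58 ± 2.46 and the recombinase gene Rag1 at 2.83 ± 0.798 TPM. The B-1 list stood at 3.44 ± 0.31, with Bhlhe41, Fcrl5, Spn and Zbtb32 at 21.6 ± 0.841, 20.9 ± 3.11, 19.6 ± 1.86 and 6.05 ± 2.20 TPM. Spn encodes CD43, the antigen used for depletion.

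Markers of cells outside the B lineage were low, apart from the myeloid and erythroid lists. The T cell list stood at 2.45 ± 1.06 log2 TPM (SD, n = 3), with Thy1 at 24.1 ± 15.98 TPM, Trbc2 at 13.7 ± 8.27, Trbc1 at 11.9 ± 9.29 and Trac at 7.79 ± 8.55 TPM. The NK cell list stood at 2.76 ± 0.21, led by Gzma, Klrk1, Nkg7 and Klrd1 between 10.7 ± 1.32 and 21.6 ± 3.12 TPM, and the dendritic list at 3.03 ± 0.48, led by Itgax at 29.7 ± 9.13, Batf3 at 12.2 ± 1.40, Clec9a at 11.7 ± 6.14 and Cd209a at 11.2 ± 4.70 TPM. The neutrophil list at 1.89 ± 0.76 was led by S100a9 at 44.4 ± 15.96, S100a8 at 29.2 ± 12.2, Csf3r at 9.10 ± 0.681 and Ngp at 5.85 ± 3.78 TPM, and the platelet list at 2.09 ± 0.55 by Ppbp, Pf4, Itga2b and Gp9 between 4.35 ± 1.56 and 11.7 ± 4.67 TPM. Of 11 stroma genes, 2 were detected, Sparc at 2.07 ± 0.515 and Cdh5 at 1.03 ± 0.0773 TPM, and the list median was -2.31 ± 0.37, a value set by undetected genes and the pseudocount, which became 0.14 with a pseudocount of 1 and 0.63 over detected members only. The myeloid list reached 5.85 ± 0.30, with the lysozyme gene Lyz2 at 386.4 ± 40.6 TPM and the complement genes C1qa, C1qc and C1qb at 164.1 ± 38.6, 108.7 ± 23.8 and 99.8 ± 27.2 TPM. The erythroid list stood at 7.74 ± 1.36.

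Of 26 differences between a mature B list and another cell type list, 24 were above 0 in all 3 samples, from 2.49 ± 0.21 for follicular B minus myeloid to 11.01 ± 0.46 for pan-B minus stroma on the log2 scale. Each of these had an exact sign-flip p of 0.25, the smallest that 3 samples allow, and an adjusted p of 0.27 over the 26, so none could pass 0.05. Pan-B minus germinal centre was 6.91 ± 0.85, pan-B minus T cell 6.25 ± 0.99 and pan-B minus plasma cell 3.96 ± 0.04. Pan-B minus erythroid was 0.97 ± 1.44, with a value below 0 in replicate 2 and an exact p of 0.50, and follicular B minus erythroid was 0.61 ± 1.43, with an exact p of 0.75. Both turned negative by CPM and by the mean over members, and the second also by exon union length and without replicate 3.

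Genes of antigen presentation, receptor signalling and B cell identity were high. All 11 MHC class II members were detected with a median of 9.82 ± 0.17 log2 TPM (SD, n = 3), with H2-Ab1, H2-Aa and H2-Eb1 at 4033 ± 506, 3932 ± 542 and 2345 ± 271 TPM. The B cell receptor signalling list had 18 of 18 members detected at 7.30 ± 0.14, including the phosphatase gene Ptpn6 at 688.4 ± 76.4 TPM and the inhibitory receptor gene Cd22 at 596.6 ± 87.9 TPM. The transcription factor list stood at 6.74 ± 0.12 with 37 of 38 detected (the exception, Pou2f1, named after its values were seen, had 10.8, 8.02 and 13.0 expected counts), led by Ets1 at 793.2 ± 111, Klf2, Spib at 493.6 ± 34.7 and Irf8 at 423.7 ± 42.7 TPM. Receptor genes stood at 6.54 ± 0.17, with Cd180 at 442.5 ± 51.8 TPM, the BAFF receptor gene Tnfrsf13c at 327.8 ± 22.5, Tnfrsf13b at 289.5 ± 17.2 and Cxcr4 at 177.9 ± 7.96 TPM.

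In most pairs of related genes, the same partner was higher in every sample. Of 21 pairs measured, 20 lay on the same side in all 3 samples, each with an exact sign-flip p of 0.25, the smallest possible. The B cell regulators Pax5 and Bach2 exceeded the plasma cell regulator Prdm1 by 5.86 ± 0.27 and 4.40 ± 0.18 on the log2 scale (SD, n = 3). Spib exceeded Spi1 by 2.26 ± 0.04, Irf8 exceeded Irf4 by 2.70 ± 0.09, Tlr9 exceeded Tlr4 by 2.21 ± 0.06, Ikzf1 exceeded Ikzf3 by 0.44 ± 0.12 and Cd79a exceeded Cd79b by 0.36 ± 0.03. Bcl6 exceeded Aicda by 3.96 ± 0.84 and Cd19 exceeded Cd3e by 7.41 ± 1.04. Ctcf exceeded Ctcfl by 8.65 ± 0.65, a ratio set by the pseudocount since Ctcfl had 3 counts or fewer. The log2 ratio of Ccr7 over Cxcr4 was -0.24 ± 0.17. Bcl2 over Bcl2l1 at 1.06 ± 1.03 and Klf2 over Mki67 at 3.77 ± 1.20 had wide spreads. In replicate 2 Bcl2 and Bcl2l1 were almost equal, at 51.0 and 50.4 TPM. Bcl2l1 and Mki67 themselves passed the test of spread between samples, and both were highest in replicate 2 and lowest in replicate 3. Foxo1 over Foxo3 was -0.33 ± 0.24 by TPM and turned to 1.34 by CPM and 1.15 by exon union length, so its direction rested on the transcript length chosen.

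Genes of resting cells and of early activation were both expressed. The quiescence list had a median of 6.17 ± 0.14 log2 TPM (SD, n = 3) with 14 of 14 detected, led by the antiproliferative gene Btg1 at 862.6 ± 69.2 TPM, Klf2, Tsc22d3 at 326.3 ± 33.0 and Slfn2 at 294.3 ± 12.4 TPM. Immediate early genes, which are also induced by tissue dissociation, had 16 of 16 detected at 7.63 ± 0.08, with Junb at 876.8 ± 50.9, Zfp36 at 657.3 ± 43.6, Fos at 364.8 ± 31.7 and Fosb at 237.6 ± 21.3 TPM. In the BCL2 family list, at 5.15 ± 0.20, Mcl1 was highest at 955.0 ± 33.8 TPM, followed by Bax at 171.0 ± 7.41, Bcl2a1b at 80.0 ± 6.44 and Bcl2 at 56.1 ± 5.61 TPM. The interferon list stood at 5.001 ± 0.28, with Stat1 at 164.6 ± 11.0, Bst2 at 93.5 ± 8.71, Rsad2 at 83.1 ± 67.7 and Irf7 at 66.2 ± 10.1 TPM. The cell cycle list stood at 4.97 ± 0.72, with Pcna at 206.2 ± 35.1, Rrm2 at 72.0 ± 54.4, Mki67 at 56.4 ± 42.0 and Mcm5 at 52.4 ± 15.7 TPM. In the sex-linked list, at -1.91 ± 0.29 with 2 of 5 members detected and 4.03 over those alone, Xist stood at 70.4 ± 9.76 TPM and Kdm5d at 3.72 ± 0.182 TPM. Uty had 6.01, 3.1 and 6.47 expected counts in replicates 1, 2 and 3, whereas Eif2s3y had 0 counts in each sample. Kdm5d has an X-linked paralog with which reads can be shared.

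Immunoglobulin transcripts were mainly of the IgM class. Ighm took 96.4% ± 1.06 of heavy chain constant counts (SD, n = 3), at 5256 ± 188 TPM, and the heavy constant list median was 4.67 ± 0.21 log2 TPM. Ighg2c at 59.9 ± 0.968, Igha at 52.7 ± 28.0 and Ighg2b at 24.9 ± 4.42 TPM followed, and Ighm exceeded Ighg2c by 6.45 ± 0.03 on the log2 scale. Igha had 1311, 514 and 648 counts in replicates 1, 2 and 3. Ighd was not analysed here, so shares of heavy chain counts leave out the IgD class. Igkc stood at 4878 ± 218 and Iglc2 at 2559 ± 183 TPM, giving a light constant list median of 11.79 ± 0.04, and Igkc exceeded Iglc2 by 0.93 ± 0.15 on the log2 scale. Iglc2 made up 37.4% ± 2.49 of the light chain constant counts, whereas lambda V segments made up 21.4% ± 3.33 of light chain V counts. Near-identical lambda constant genes share reads, and Iglc1, Iglc3 and Iglc4 were not analysed here, so the constant share is uncertain. The Ighv1 family took 53.1% ± 0.411 of heavy chain V counts, followed by Ighv5 at 9.52% ± 0.504 and Ighv2 at 6.38% ± 0.300.

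Erythroid genes differed most between samples. In edgeR's quasi-dispersion test, 84 of 12206 genes varied by more than genes of their abundance at an adjusted p under the threshold of 0.05, and 82 of the 84 were highest in replicate 2 and lowest in replicate 3, an order shown by 20.8% of all genes tested. The 20 with the largest F included genes of the red cell membrane and blood groups (Sptb, Gypa, Ank1, Slc4a1, Spta1, Dmtn, Rhd, Rhag, Kel, Ermap and Aqp1), carbonic anhydrase (Car2), heme synthesis (Alas2), and Snca, Tmcc2, Trim10, Btnl10 and Rsad2, together with the proliferation genes Mki67 and Rrm2. Sptb, which encodes erythroid beta-spectrin, had 127.4, 328.6 and 44.7 normalized CPM in replicates 1, 2 and 3 (adjusted p = 0.0175, edgeR), and Slc4a1, the band 3 anion exchanger gene, had 589.3, 1542 and 210.6. The exceptions were Igha, highest in replicate 1 (adjusted p = 0.0415, edgeR), and a gene without a symbol, ENSMUSG00000090407, which had 25.5, 1.61 and 20.7 normalized CPM. The common biological coefficient of variation was 14.9%. Without the robust option edgeR called 0 genes, with 679 at an unadjusted p under 0.05, while limma voom called 65 and DESeq2 listed 237 dispersion outliers. Leaving out replicates 1, 2 and 3 in turn gave 34, 176 and 0 genes by edgeR, with 713 at an unadjusted p under 0.05 in the last case.

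By list, all 9 erythroid members passed over all genes, and 9 of 9 when adjusted over the list alone. Of the 17 cell cycle members, 5 passed over all genes (Mki67, Rrm2 and, named after their values were seen, Ccna2, Birc5 and Top2a) and 17 when adjusted over the list alone, and all 17 were highest in replicate 2 and lowest in replicate 3. Of 10 T cell genes tested, 0 passed over all genes by edgeR and 9 when adjusted over the list alone, with 9 at an unadjusted p under 0.05, and all 10 were highest in replicate 3. Igha, Bcl2l1 and Rsad2 were the members of the heavy constant, BCL2 family and interferon lists that passed over all genes. Esco2 passed only when adjusted over the CTCF and cohesin list alone. None of the 16 pan-B or 11 follicular B members passed over all genes or over the list alone, and none had an unadjusted p under 0.05.

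The lists whose members moved together in a sample were erythroid, cell cycle, interferon and T cell, each at percentile 100 of 10000 matched random lists. The mean deviation of the erythroid list was 1.24 in replicate 2 and -1.35 in replicate 3 on the log2 scale, that of the cell cycle list 0.70 and -0.83, and that of the interferon list 0.39 and -0.51. Of the 11 interferon members, 8 were highest in replicate 2 and 3 in replicate 1, and 2 passed when adjusted over the list alone, Rsad2 and Isg15, the latter named after its values were seen. Their log2 ratios of replicate 2 over replicate 3 were 2.78 and 2.10, against a list median of 0.58. The T cell list deviated by -0.92 in replicate 1 and 0.89 in replicate 3. The pan-B, follicular B and transcription factor lists stayed at percentiles 62.7, 61.9 and 35.8, and the largest deviation of any of them in a sample was 0.05. Germinal centre genes were highest in replicate 1 in 9 of 9 cases after TMM normalization. Without it, Bcl6 was highest in replicate 3, at 122.5 CPM against 119.5 in replicate 1. The mean deviation of the germinal centre list in replicate 1 was 0.54. That list and the neutrophil, CTCF and cohesin, platelet and heavy constant lists also lay above the central 95% of random lists, 9 of 25 lists in all. Their percentiles fell to 75.0 for germinal centre, 80.6 for platelet and 66.9 for heavy constant without replicate 1, 59.8 for neutrophil without replicate 2, and 80.9 for CTCF and cohesin without replicate 3. With library totals, CTCF and cohesin lay at 96.3. The median SD of the members of that list was at percentile 34.1, and Esco2 and Cdca5 had TMM-normalized log2 ratios of replicate 2 over replicate 3 of 2.31 and 1.53, against 0.05 for Ctcf.

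**Figure D2:**
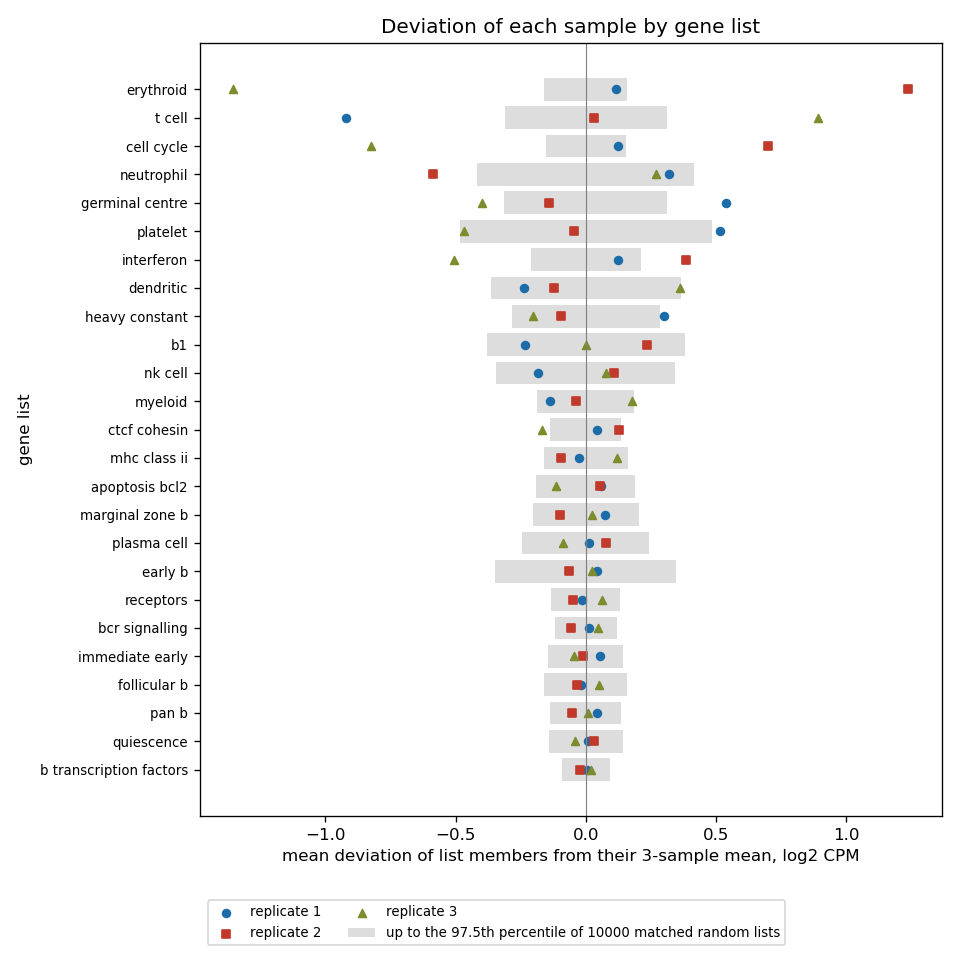
Mean deviation of the members of each list from their mean over the 3 samples, in log2 CPM on the horizontal axis, with a point per sample and a grey bar for the range of matched random lists. The erythroid list spans -1.35 in replicate 3 to 1.24 in replicate 2, while the points of the pan-B list lie inside its grey bar.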

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

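Exon union lengths, the erythroid covariate and the removal of globin genes were chosen after seeing the data. The number of genes detected, of list medians of at least 1 TPM, of gene pairs on the same side and of lists above the central 95% of random lists stayed within 1.5 times under the alternatives run. The levels themselves moved more: 64 of 224 alternative list levels differed from the reported one by more than the SD between samples. By CPM the erythroid level went from 7.74 to 9.17 and the light constant level from 11.79 to 10.22, and over detected members only the early B level went from -0.26 to 3.62. Of 208 alternative values of the list differences, 202 kept their direction. Pan-B minus erythroid turned to -0.21 by CPM and -0.35 by the mean over members, and follicular B minus erythroid to -0.40 by CPM, -0.80 by the mean over members and -0.41 by exon union length, and ranged from -0.12 to 1.31 with each replicate left out. Foxo1 over Foxo3 turned to 1.34 by CPM and 1.15 by exon union length, both of which change only the length used. By shares of TPM, the top 50 genes held 25.6%, lambda 34.4% of light chain constant transcripts and Ighv1 53.8% of heavy chain V transcripts.

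The count of 84 variable genes in edgeR became 133 with library totals, 738 with no filter on low counts, 237 as DESeq2 dispersion outliers, 9 with the erythroid covariate and 0 without the robust option, where 679 genes had an unadjusted p under 0.05 and limma voom called 65. With each replicate left out it ranged from 0 to 176. All 84 genes were called again with library totals and with no filter, and 2 of them with the covariate. The erythroid covariate was the mean log2 CPM of Alas2, Gypa, Klf1, Slc4a1 and Ermap, all among the 84 genes. With it the common coefficient of variation went from 14.9% to 7.77%. It was built from genes of the pattern itself and takes up a degree of freedom. The fall to 9 genes and to 7.77% was thus partly built in and tests no cause. The cause of the other changes was not tested, except that fewer samples remain when a replicate is left out. Of 146 alternative percentiles of list deviations, 130 stayed on their side of the central 95%, 9 moved above it and 7 fell inside it. With at least 50 counts in each sample, the germinal centre, neutrophil, platelet and T cell lists had too few members left to give one. Depth limited values of genes under 10 counts, and 3 samples limited the spread test, which recovered 0% of simulated 2-fold differences among 12206 genes.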

Other observations

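The tests of library depth, with and without the globin genes, of cycling erythroid precursors and of germinal centre genes in replicate 2 over replicate 1 were chosen after the results were seen. The 3 samples formed 1 group, so no explanation by a difference between groups was tested, and the tests bear on the mix of cells in the samples and on the counting of reads.

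The 4 adult globin genes differed between samples, with a median log2 ratio of replicate 2 over replicate 3 of 2.24 (SD 0.07 over genes). Reads shared between near-identical globin copies were argued against by 5 erythroid genes that are not globins (Alas2, Gypa, Klf1, Slc4a1 and Ermap), whose median log2 ratio was 2.80 (SD 0.21). Library depth was argued against by the erythroid list lying at percentile 100 of random lists of matched abundance, where these 5 genes alone also lay. RNA of residual red cells remains a candidate explanation, since those same 5 genes reached the bound of 1 set in advance. The protocol does lyse erythrocytes. These 5 genes cannot tell red cells from erythroid precursors, and whether either was removed with CD43-bearing cells was not tested. The most abundant globin gene, Hba-a2, had 41039, 78660 and 22458 counts in replicates 1, 2 and 3.

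Cell cycle genes followed the order of the globin genes. Cells of the T, myeloid and neutrophil lineages were argued against by their list medians of the log2 ratio of replicate 2 over replicate 3, the highest of which was -0.30 (SD 0.25, myeloid). For germinal centre B cells, the median of 7 genes was 0.25 (SD 0.43), too wide to decide by the bound of 0.5, but all 9 members were lower in replicate 2 than in replicate 1, with a median of -0.64 (SD 0.31), whereas cell cycle genes were higher there by 0.53 (SD 0.31). Cycling erythroid precursors and cycling B cells in replicate 2 cannot be told apart: either would place the cell cycle genes in the order seen, in which 17 of 17 were highest in replicate 2 and lowest in replicate 3.

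Igha and Ighg1 counts were highest in replicate 1, at 1311, 514 and 648 for Igha and 40, 6 and 9 for Ighg1, which was named after its values were seen. More plasma cells in replicate 1 could not be told apart from no change: 5 plasma cell genes (Sdc1, Jchain, Prdm1, Tnfrsf17 and Derl3) had a median log2 ratio of replicate 1 over the others of 0.13 (SD 0.15). This missed the 0.5 set in advance as needed and lay below the 0.2 set as the opposing bound by less than the spread. Plasma cells carry CD43, the antigen used for depletion, but how completely they were removed was not measured. Jchain stood at 290.6 TPM in these samples, a baseline that can hide a small share of plasma cells. The 9 germinal centre genes were also higher in replicate 1, with a median log2 ratio over the others of 0.68 (SD 0.44). Whether this was linked to the Igha and Ighg1 counts was not tested.

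The lambda share of light chain V counts was 25.04%, 20.6% and 18.5% in replicates 1, 2 and 3, beside constant shares of 40.3%, 36.0% and 36.0%. Whether reads lost from or moved between light chain constant genes raised the constant share was left undecided. The V shares met neither the low nor the high bound set in advance, each of which had to hold in every sample. V segments share reads too, so both shares are uncertain.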
